A study of Mus musculus with 4 samples.

How the data were processed

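The series holds 4 samples of mouse brain, a gene expression and an ATAC library from a mock-infected and from an MCMV-infected source. Per the labels' protocols, mice were perfused, brains were flash frozen, nuclei were freed by lysis and homogenisation, myelin was removed on a Percoll gradient, and libraries were made with the 10x Multiome kit. Groups were taken from the sample titles and the treatment labels; the mock samples are called mock in their titles and untreated in their treatment label. The number of mice behind each library is not given in the sources used here. The deposited data used here are, for each library, the list of called nucleus barcodes and the list of features, which holds gene identifiers with symbols and the positions of ATAC peaks. None of these holds a measured value, and a peak has a position and a width but no score. They were made with Cell Ranger ARC 2.0.0 and the mm10 build, per the submitters' processing notes; the settings of cell and peak calling are not given in the sources used here. The 2 peak lists differ in number and position. Matrices of counts were not analysed here, so doublets were neither called nor removed; how the submitters treated doublets is not given in the sources used here.

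Both lists of each library were assigned by a library number, 7 or 8, which the sample descriptions repeat, and no other label ties them to a group. Peak positions are printed as the deposited lists write them, and the width is the end minus the start. Peaks on chromosomes 1 to 19 and X were used; 111 peaks on Y or unplaced contigs in both libraries together were kept apart. Gene positions came from the RefSeq gene table of the same mouse assembly as mm10, matched by symbol: 26136 symbols that occur once in the feature lists, 81.0% of the 32285 gene rows, had a position on these chromosomes. The planned use of transcription start sites was replaced, since the feature lists and the gene table gave no start site or strand: a gene-end peak is a peak within 1000 bp of either end of the gene's interval, so it may mark the end of transcription, and windows of 50 kb were laid around the gene's whole interval. Exons were not used.

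Peaks of both libraries were compared by overlap of at least 1 bp, and the shares were set beside those after 100 circular shifts along each chromosome. Shares have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. The gene lists, 34 in number with 517 genes, were fixed before the data were examined; 513 of the genes were measured, and Clec7a, Cxcl11, Mx1 and Mx2 were not. For each list the mean over genes of MCMV minus mock peaks within 50 kb, with MCMV peaks scaled to the mock total, was placed among 10000 random lists of the same size drawn within 20 bins of mean peak number from the 22981 genes with a peak in their window. A list below the percentile 2.5 or above 97.5 was taken as outside the central 95%, which describes these 2 libraries and is no test of infection. No p-value was computed. The number of random lists with as many single-library gene-end peaks, and the gene-end calls of single listed genes under other settings, were computed after the data were seen.

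The text names every listed gene with a gene-end peak in a single library. It also names, per direction, the 12 genes with such a peak and the largest excess of peaks within 50 kb before scaling. Ties were ordered by peak width and then symbol, and predicted genes, Rik, microRNA and olfactory receptor genes were left out. The genes of the 5 windows of 100 kb with the largest excess per direction are named too, at most 3 per window. Other named genes are examples of their list, chosen after their values were seen.

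The overlap and list steps were tested on data simulated from the mock peaks over 26136 genes. A planted overlap of 79.94% was recovered as 79.96%. Kept peaks were moved only slightly and new ones were placed in wide gaps, so this checks the calculation only. Of 100 lists of 15 genes given 2 extra peaks per gene, 97% lay above the percentile 97.5, and 6% of 100 unchanged lists lay outside the central 95%. These lists were drawn at random and the extra peaks were added gene by gene. The rates therefore do not cover lists of neighbouring genes that share peaks. The alternatives kept wider peaks, equal peak numbers or merged neighbours, left out X, asked for 50% reciprocal overlap or allowed gaps of 500 bp, used gene-end distances of 200 and 5000 bp, windows of 10, 200 and, for the genome, 200 kb, unmatched random lists, and no scaling. After the data were seen, counting each peak once per list, leaving out list members, using gene bodies and using protein-coding genes were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.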

Results

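The series asked how the brain of old mice differed after repeated infection with murine cytomegalovirus (MCMV), a betaherpesvirus that persists for life in its host. Female BALB/c mice were mock-infected or given 50000 plaque-forming units of the MCMV Smith strain at 8 weeks of age, with further infections every 3 months. Brains were collected at 14 months of age, 12 months after the first infection. Nuclei were profiled with the 10x Multiome assay, which reads open chromatin (ATAC) and RNA from the same nucleus. There was 1 library per group, so the groups had no replicates, no test of the infection was possible, and every difference given here is between 2 libraries. The mock library held 20000 called nuclei and the MCMV library 7798, or 61.0% fewer. The same 32285 genes were listed in both libraries. The values compared below are the positions of the ATAC peaks called in each library: 94768 in the mock library and 89805 in the MCMV library on chromosomes 1 to 19 and X. Counts per nucleus and the depth behind each peak were not analysed here, so the lists show where chromatin was called open and not how open it was. The match of lists to libraries rests on a library number, 7 for mock and 8 for MCMV, that the sample descriptions also carry.

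The peak maps of both libraries were compared first. Genes that every cell uses and genes of neuronal activity and synapses were marked in both. All 16 housekeeping genes, all 16 immediate early genes such as Fos and Arc, 23 of 26 synaptic genes and 12 of 14 excitatory neuron markers had a peak within 1000 bp of a gene end in both libraries. Markers of tissues other than brain had such a peak in both libraries for 4 of 16 genes, and in neither for 12. Of the mock peaks, 79853 overlapped an MCMV peak by at least 1 bp, or 84.3% (exact binomial 95% interval 84.0 to 84.5%). Of the MCMV peaks, 79835 overlapped a mock peak, or 88.9% (88.7 to 89.1%). After 100 random circular shifts of the peaks along their chromosomes these shares averaged 6.00% (SD 0.12) and 6.31% (SD 0.11). The remaining 14915 peaks were found in the mock library only and 9970 in the MCMV library only. The MCMV library had 0.948 times the peaks of the mock library (0.939 to 0.956), covering 77.5 Mb against 81.4 Mb, with a mean width of 863 bp against 859 bp. All intervals cover counting error only.

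Peaks found in a single library lay at gene ends less often than shared peaks. Of the shared peaks, 20.9% were within 1000 bp of a gene end, against 8.72% (8.27 to 9.19%) of the mock-only peaks and 7.92% (7.40 to 8.47%) of the MCMV-only peaks. A circular shift placed 5.13% of mock peaks and 5.10% of MCMV peaks there. Elsewhere within genes lay 46.3% of shared peaks, 59.7% of mock-only peaks and 60.3% of MCMV-only peaks. The median width was 879 bp for shared and 846 bp for mock-only peaks of the mock library, and 880 bp and 848.5 bp in the MCMV library. Over 79649 pairs of peaks that each overlapped a single peak of the other library, the median log2 ratio of widths, MCMV over mock, was 0.0017 (interquartile range -0.030 to 0.035). Among 34 gene lists, the median log2 ratio of the gene-end pairs lay between -0.06, for 11 pairs at cytokine and chemokine genes, and 0.03, for 12 pairs at inhibitory neuron markers.

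**Figure D1:**
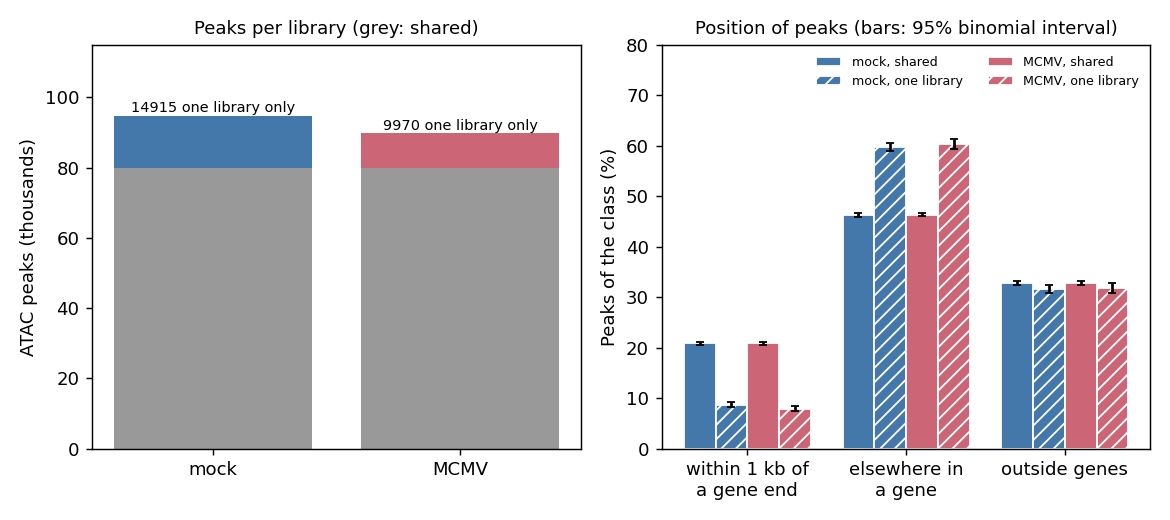
Left, ATAC peaks on chromosomes 1 to 19 and X per library (axis in units of 1000), with shared peaks in grey and peaks of a single library in colour. Right, percent of shared and single-library peaks (hatched) by position, with exact binomial 95% intervals; 8.72% of mock-only and 7.92% of MCMV-only peaks were within 1000 bp of a gene end, against 20.9% of shared peaks.

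The next comparison asked which genes had a gene-end peak in a single library. Among genes of inflammation and antiviral defence, the MCMV library alone had one at Ccl7, a chemokine that attracts monocytes, at Oas2, an interferon-induced sensor of viral RNA, and at Nfkb2, a subunit of NF-kB. The mock library alone had one at Ddx58, which encodes the RNA sensor RIG-I, at Spp1 and Cd44, both raised in reactive glia, and at the T cell genes Tbx21 and Cd5. As many MCMV-only calls were held by 19.64% of random lists for cytokines, 35.13% for interferon-stimulated and 18.82% for NF-kB genes. As many mock-only calls were held by 57.42% for interferon-stimulated and 29.71% for disease-associated microglia genes. For reactive astrocyte genes this was 37.12%, and for T and NK cell markers 12.97%. The number of calls in these lists can therefore not be told apart from chance. At the ends of Ccl7 lay MCMV-only peaks at chromosome 11, 82045263 to 82046161 and 82047535 to 82048655 (mm10). At Oas2 it lay at chromosome 5, 120729068 to 120729949, 4455 bp from the nearest mock peak. The mock peak at Ddx58 lay at chromosome 4, 40238628 to 40239277, 28797 bp from the nearest MCMV peak. Of 26136 genes, 15765 had a gene-end peak in both libraries, 531 in the mock library only, 299 in the MCMV library only and 9541 in neither. The MCMV library had 89805 peaks, so equal peak numbers were reached by dropping the narrowest mock peaks only. The counts were then 475 and 508, which turns their order around. Dropping mock peaks can only lower the mock-only count and raise the MCMV-only count. Ccl7 kept its MCMV-only call under all 6 other settings of peaks and distance. Leaving out X and cutting the mock list could not have ended this call. Nor could merging peaks less than 500 bp apart, since the nearest mock peak lay 11309 bp from its widest end peak. The cut on peak width and the distances of 200 bp and 5000 bp did test it. Oas2 lost its MCMV-only call at 200 bp and at 5000 bp, and Nfkb2 at 5000 bp and with only peaks at or above the median width. Ddx58 lost its mock-only call at 200 bp, with equal peak numbers and with the wider peaks. Spp1, Tbx21 and Cd5 lost theirs at 5000 bp and with the wider peaks, and Cd44 with the wider peaks. The gene-end peak of 22 of the 531 genes and 23 of the 299 overlapped a peak of the other library that stopped short of the gene end.

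Across the lists fixed before the data were examined, 28 of 513 measured genes had a gene-end peak in a single library, 19 in the mock library and 9 in the MCMV library. With equal peak numbers, where only the mock list was cut, these counts over the listed genes were 17 and 18. With only peaks at or above the median width they were 39 and 31. This cut on width can split a shared pair of peaks of nearly equal width and so make new single-library calls. Of the 28 genes, 11 of the 19 and 1 of the 9 kept their call with a distance of 5000 bp, 12 and 4 with one of 200 bp, and 5 and 2 with only these wider peaks. Inhibitory neuron markers had 3 of 14 in the mock library only, namely Sst, which encodes somatostatin, and the interneuron transcription factors Lhx6 and Dlx1, with 10 in both and 1 in neither. Random lists of the same size held 0.36 such genes on average, and 0.38% of them held as many. Mural cell markers also had 3 of 11 in the mock library only, Notch3, Tagln and Tbx18, against 0.30 in random lists, of which 0.26% held as many; the Tbx18 peak lay 113 bp from an MCMV peak. With a distance of 5000 bp no mural cell marker was left, while the inhibitory markers Lhx6 and Sst kept their mock-only call. The inhibitory markers had 2 in the mock and 1 in the MCMV library only with equal peak numbers, and 0 and 2 with only the wider peaks. With a distance of 200 bp the mural list had 1 in the mock library only. The inhibitory list then had 2 in the mock and 1 in the MCMV library only. Astrocyte markers had 2 of 15 in the MCMV library only, the gap junction gene Gja1 and the bicarbonate transporter Slc4a4, and 1 in the mock library only, Acsbg1; at 5000 bp and with only the wider peaks 0 were left in the MCMV library only. The MCMV-only peaks at Cdh5 of endothelium, at P2ry12 of microglia and at Th, the rate-limiting enzyme of dopamine synthesis, lay 164, 191 and 106 bp from a mock peak. Other listed genes with a mock-only gene-end peak were the dopamine transporter Slc6a3, Lmx1a of midbrain neurons, Nkx6-2 of oligodendrocytes, Sox17 of endothelium, Rarres2 of choroid plexus, Nr2e1 of neural stem cells and the hexokinase gene Hk1. Aspg, a gene of reactive astrocytes, had an MCMV-only one.

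Outside the lists, the genes with a mock-only gene-end peak and the largest excess of mock peaks within 50 kb were led by Ntrk3, the receptor of neurotrophin-3, with 32 mock against 23 MCMV peaks. Kcnh1, a voltage-gated potassium channel, had 30 against 22, and Hif1a, the oxygen-regulated transcription factor, had 15 against 8. All 7 mock-only peaks near Hif1a lay between 73862647 and 73990363 of chromosome 12. The neighbours Tmem239 and Cpxm1 had 14 against 7 and 13 against 6. Kat6b (24 against 18), Dnah8 (22 against 16), St6gal1 (14 against 8), Siglec15 (11 against 5), Gpr12 (10 against 4), Dlc1 (19 against 14) and Figla (15 against 10) completed this group. The mock peak at the end of Kat6b overlapped an MCMV peak that lay beyond the distance limit.

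In the other direction Il16, which encodes a chemoattractant of T cells, had 16 mock against 20 MCMV peaks, and Pstpip1, an adaptor protein of blood cells, had 8 against 12. The MCMV-only end peak of Il16 lay 266 bp from a mock peak. Zfp800 had 9 against 13. The chemokine genes Ccl7 and Ccl11 each had 3 against 6, from the same 3 MCMV-only peaks between 82045263 and 82058220 of chromosome 11. These peaks also gave Ccl2 its 3 against 6. The homeobox gene Lhx1 and its neighbour Lhx1os shared an end peak and had 5 against 8. Gpr182 (5 against 8), the drug transporter Slc47a1 (6 against 9), Rgs13 (4 against 7), the retinoic acid hydroxylase Cyp26b1 (8 against 11) and the connexin Gja6 (0 against 3) completed this group.

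Gene lists were then compared by the number of peaks within 50 kb of their genes, with MCMV peaks scaled to the mock total. In all lists a peak near several members was counted for each of them, while random lists were drawn gene by gene. The list of MHC class I and antigen processing genes had 149 mock and 159 MCMV peaks, a mean difference per gene of 1.25 and a percentile of 99.86 among 10000 matched random lists. Of its 15 members 8 had more MCMV peaks, 4 fewer and 3 the same number before scaling. Psmb8 and Psmb9 of the immunoproteasome had 12 against 15 each, and the peptide transporter genes Tap1 and Tap2 had 13 against 16 and 14 against 16. The joined windows of these 4 neighbours hold 4 MCMV-only peaks, the outermost at 34144972 to 34145894 and 34205542 to 34206467 of chromosome 17, and 1 mock-only peak; 2 of the MCMV-only peaks lie within 50 kb of all 4 genes. With each peak counted once the list had 106 peaks in each library and a percentile of 84.9, and with a 10 kb window a mean difference of 0.416 and a percentile of 96.2, both inside the central 95% of random lists. A gene-end peak was found in both libraries at 14 of 15 members, and with only the wider peaks at 5, with 2 in the mock and 1 in the MCMV library only.

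Dentate gyrus and hippocampus markers had 107 mock and 120 MCMV peaks, a mean difference of 2.18 and a percentile of 99.98. More MCMV peaks were found at 5 of the 9 genes, fewer at Calb1 and the same number at 3. Zbtb20, a zinc finger gene of hippocampal pyramidal and granule neurons, had 34 mock against 42 MCMV peaks, with 12 MCMV-only and 4 mock-only peaks in the gene or within 50 kb of it. Dsp, which encodes desmoplakin, had 5 against 8, and Prox1 of granule cells had 7 against 8. Without Zbtb20 the mean difference was 1.16 and the percentile 97.9, and with only peaks at or above the median width it was 90.5, inside the central 95%.

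Monoamine and neuropeptide neuron markers went the other way, with 123 mock and 105 MCMV peaks, a mean difference of -0.81 and a percentile of 2.12. Before scaling, no member had more MCMV peaks, 7 had fewer and 9 had the same number; after scaling, 8 of the 15 members with a peak had more. Dbh, which makes noradrenaline, had 19 mock against 12 MCMV peaks, all 7 of the difference mock-only, and the noradrenaline transporter Slc6a2 had 9 against 6. The neuropeptide genes Avp and Oxt each had 2 fewer MCMV peaks. The percentile lay within the central 95% for 6 of 7 other settings, and with only peaks at or above the median width the mean difference was 0.20.

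**Figure D2:**
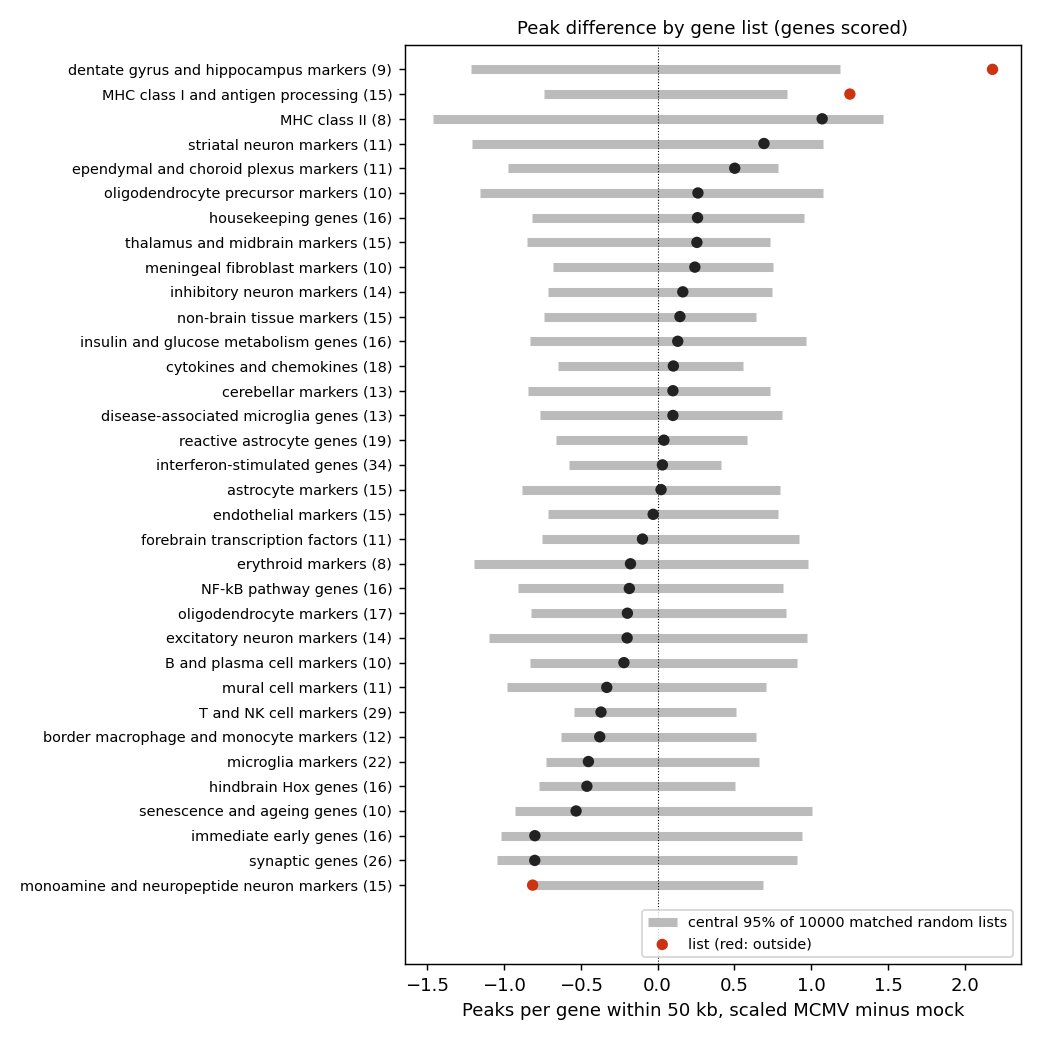
Mean difference in peaks per gene within 50 kb (scaled MCMV minus mock) of 34 gene lists, as points, with the central 95% of 10000 matched random lists as grey bars and the number of genes scored in brackets. The 3 red points lie outside their bar; chance gives 1.7 of 34.

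The other 31 lists lay within the central 95% of random lists. Interferon-stimulated genes had 287 mock and 273 MCMV peaks and a percentile of 69.4, with gene-end peaks in both libraries at 24 of 36 measured genes, among them Irf7 and Usp18. MHC class II genes had 117 against 119 peaks (percentile 92.3), cytokines and chemokines 110 against 106 (72.2), and NF-kB pathway genes 176 against 164 (37.6). With a 200 kb window the class II genes had a mean difference of 4.85, above the central 95%, and the cytokines went from 0.10 to -1.59, with a percentile of 0.685. Most class II genes are neighbours on chromosome 17, so such wide windows count the same peaks several times. With each peak counted once at 50 kb, the class II genes had 69 peaks in each library (80.1) and the cytokines 94 against 89 (46.0). T and NK cell markers had 227 against 205 peaks (8.98), with a gene-end peak in neither library at 23 of 31 genes, and B and plasma cell markers 75 against 69 (24.9), with 7 of 10 in neither. Microglia markers had 241 against 219 (10.7), genes of disease-associated microglia 100 against 96 (58.1), and border macrophage and monocyte markers 52 against 45 (11.2).

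Among glia and vessels, astrocyte markers had 159 mock and 151 MCMV peaks (percentile 53.9), reactive astrocyte genes 148 and 141 (61.0), oligodendrocyte markers 207 and 193 (31.9), and oligodendrocyte precursor markers 124 and 120 (68.5). Endothelial markers had 126 and 119 (43.2), mural cell markers 87 and 79 (29.8), meningeal fibroblast markers 44 and 44 (70.9), and ependymal and choroid plexus markers 81 and 82 (90.2). Among neurons, immediate early genes had 208 and 185 (6.41), with fewer MCMV peaks at 13 of 16 genes such as Npas4 (17 against 14) and Nr4a1 (18 against 15). Synaptic genes had 636 and 583 (6.65), with fewer at 19 of 26, such as Nrxn3 (82 against 74) and Ntrk2 (39 against 33). Excitatory neuron markers had 179 and 167 (36.2), inhibitory ones 99 and 96 (65.9), striatal ones 138 and 138 (89.9), cerebellar ones 100 and 96 (62.8), and thalamus and midbrain markers 146 and 142 (78.3). Forebrain transcription factors had 76 and 71 (32.0) and hindbrain Hox genes 96 and 84 (13.5). The Hox genes had percentiles of 1.52 with equal peak numbers and 0.52 with only the wider peaks. These values count peaks shared by neighbouring Hox genes more than once. With all peaks and each counted once, 4 Hox loci had 34 and 29 peaks (14.5). Synaptic genes had a percentile of 0.82 when random lists were not matched on peak number. Housekeeping genes had 190 and 184 (65.7), erythroid markers 70 and 65 (42.6) and markers of tissues other than brain 116 and 112 (68.0).

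Peaks were also counted in 100 kb windows. The window with the largest excess in the MCMV library, chromosome 17 from 27500001 to 27600000, had 14 mock and 20 MCMV peaks and holds Grm4, a metabotropic glutamate receptor, with Hmga1 and Nudt3. Windows at Xkr6 on chromosome 14 and at Xxylt1 and Acap2 on chromosome 16 each had 7 against 13, the window at Frmd5 on chromosome 2 had 4 against 10, and that at Igsf21 on chromosome 4 had 12 against 17. The largest excess in the mock library, 17 against 9 peaks, was on chromosome 12 from 25000001 to 25100000, at Id2, an inhibitor of helix-loop-helix transcription factors, and Kidins220. The windows of Itga8 and Mindy3 on chromosome 2 (10 against 3), Nfatc1 and Atp9b on chromosome 18 (11 against 4), Tbc1d9 on chromosome 8 (13 against 6) and Spock1 on chromosome 13 (14 against 7) followed. Of 18711 windows with a peak, 45.5% had equal numbers in both libraries and 1157 differed by more than 2 peaks.

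**Figure D3:**
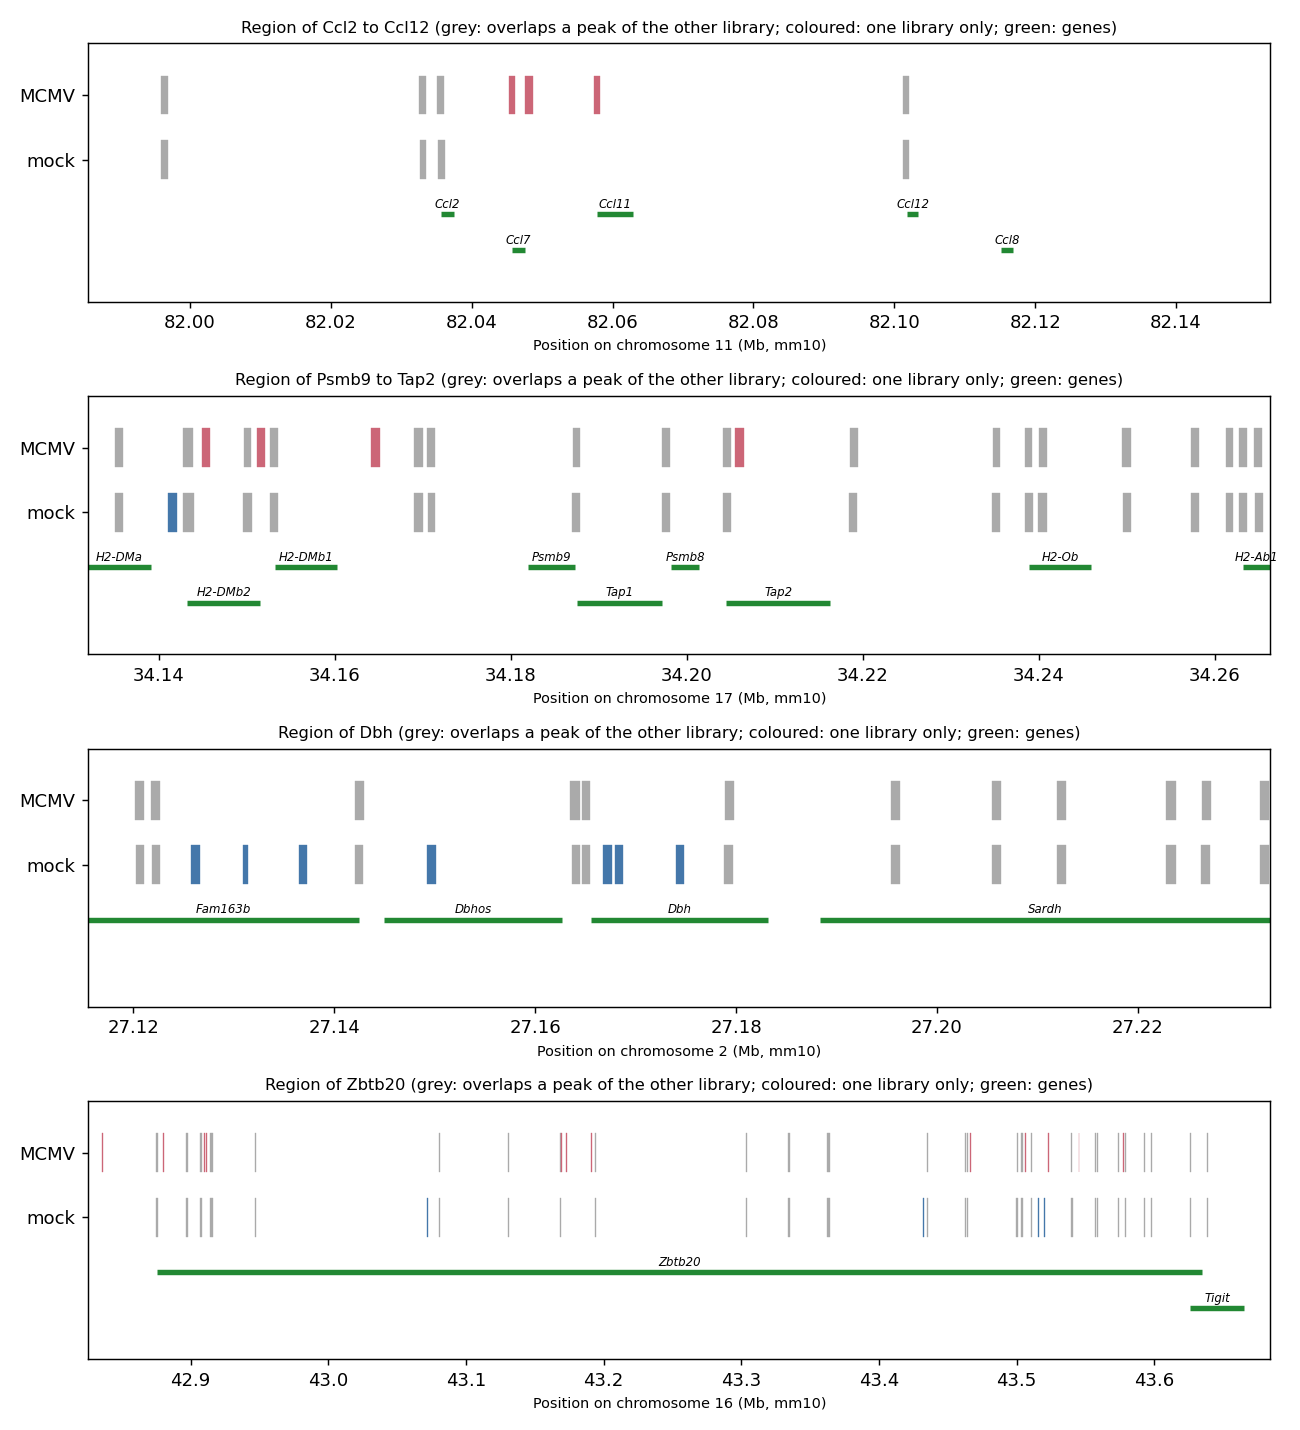
Peaks of both libraries along 4 regions (position in Mb, mm10), in grey where they overlap a peak of the other library and in colour where they do not, with gene intervals in green. The chemokine region holds 3 MCMV-only peaks, the region from Psmb9 to Tap2 holds 4 MCMV-only and 1 mock-only, that of Dbh 7 mock-only, and that of Zbtb20 12 MCMV-only and 4 mock-only.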

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

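Counting each peak once per list, leaving out list members, gene bodies and protein-coding genes were alternatives chosen after the data were seen; the others were planned. With only peaks at or above the median width of 877 bp, the MCMV library had 0.987 times the peaks and 0.988 times the covered length of the mock library, 71.3% of mock and 72.2% of MCMV peaks were overlapped, and 1228 and 1223 genes had a gene-end peak in the mock or the MCMV library only. The interquartile range of widths was 830 to 905 bp in the mock and 835 to 907 bp in the MCMV library. This cut can therefore keep 1 peak of a shared pair of nearly equal width and drop the other, which adds single-library calls. With the widest 89805 peaks of each library, the ratio of peak number was 1 by construction, that of covered length 0.986, the overlapped shares 85.5% and 85.6%, and 508 genes had an MCMV-only gene-end peak. The MCMV library had no more than 89805 peaks, so only the mock list was cut, which can only raise the MCMV-only count. Merging peaks less than 500 bp apart gave 85.5% and 89.6%, and counting peaks up to 500 bp apart as shared gave 86.3% and 90.3%. A peak anywhere in the gene body left 353 mock-only genes, and the 20522 protein-coding genes held 196 MCMV-only genes, 0.955% of them against 1.14% of all genes. The 3 lists outside the central 95% became 6 with a 200 kb window (class I, class II, hippocampal and striatal above, border macrophage and cytokine below) and 1 with each peak counted once. At 200 kb, neighbouring genes of a list share more peaks. Of the 10 named windows, 5 were found again with 200 kb windows and 4 with equal peak numbers. The monoamine and neuropeptide list had a mean difference of 0.20 with only the wider peaks, and the cytokine list one of -1.59 with a 200 kb window. Of 238 list values under alternatives, 221 stayed on their side of the central 95%, 8 moved outside and 9 moved inside; 55 changed sign, of which 2 (those named) were outside in either setting. Except where the construction is named, the cause was not tested. Leaving out replicates and a paired analysis had no place with 1 library per group. Depth per peak was unknown, so peaks missing from a list may lie just under the calling limit.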

Other observations

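The tests of single-library peaks without a near neighbour, of gene-end calls against random lists, of members left out and of peaks counted once were chosen after the results were seen; the examples named in these first 2 paragraphs were also chosen after their values were seen. Genes of insulin signalling and glucose use had 210 mock and 201 MCMV peaks within 50 kb (percentile 54.4), with 15 of 16 gene-end calls in both libraries. Within this list the members went both ways. The hexokinase gene Hk2 had 13 mock against 7 MCMV peaks and the insulin receptor gene Insr 7 against 4, while Irs1, an adaptor of the insulin receptor, had 9 against 12 and Foxo1 12 against 14. Senescence and ageing genes had 95 and 85 peaks (percentile 11.1), and 10 of 12 had a gene-end peak in both libraries; with a 10 kb window the percentile was 0.905.

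Of 22 microglia markers 4 had more and 13 fewer MCMV peaks before scaling, and 9 had more after it. The neighbouring complement genes C1qa, C1qb and C1qc each had 3 more MCMV than mock peaks (14 against 17 at C1qa), while the neighbours Tmem119 and Selplg each had 6 fewer (18 against 12 at Tmem119), and Irf8 had 8 against 5. Among T cell genes Cd8a had 8 against 2 and Cxcr6 5 against 7. On the Y chromosome each library had 12 peaks, 11 of them overlapped by the other library, although the mice are labelled female.

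Peaks found in a single library numbered 0.668 in the MCMV library for each 1 in the mock library. This is above the bound of 0.5 set against the smaller number of MCMV nuclei as the cause, but that bound left out peaks near the calling limit, which chance can place in either library, and without depth per peak this explanation stays open. Relative to shared peaks, these peaks lay at gene ends 0.418 times as often in the mock library and 0.379 times in the MCMV library. This was predicted if many of them lay close to the calling limit. Peaks that truly differ but lie away from gene ends would give it too. Without a score per peak, position cannot tell these explanations apart. A shift of peak position between the 2 calls stays open for the 13.1% with a peak of the other library within 500 bp. The same count leaves 86.9% with none that near. By definition those cannot come from a shift of up to 500 bp, so the 86.9% is no separate test. A difference in chromatin after infection also stays open, as untested without replicates.

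Of the lists outside the central 95% of random lists, the MHC class I list fell to the percentile 84.9 with each peak counted once, so its excess may come from neighbouring genes that share peaks. The hippocampal list stayed outside when any 1 member was left out, with a lowest percentile of 97.9, which argues against a single gene as its whole cause, but without Zbtb20 its mean difference was 1.16 in place of 2.18. A different share of non-neuronal cells stays open. In the main and every other setting, 0 of 8 such lists lay outside the central 95%, but that count leaves out gene-end calls. Among the gene-end calls, mural cell markers (0.26% of random lists) and astrocyte markers (2.24%) were among 4 of 68 values under 2.5%, where chance gives up to 1.7. The others were the inhibitory (0.38%) and forebrain (2.28%) lists, which share the mock-only gene Dlx1, so the 4 values are not independent. At 5000 bp the mural list had no mock-only and the astrocyte list no MCMV-only call left. At 200 bp they had 1 and 2, though Gja1 had lost its call, and with only the wider peaks 2 and 0. With equal peak numbers the mural list kept 3. Of the region lists, 1 of 6 lay outside. As many mock-only gene ends as in the forebrain list were held by 2.28% of random lists, and at 5000 bp the forebrain list had 0 left. Of the immune lists, 1 of 8 lay above. With other settings these counts of lists ran from 1 to 2 and from 0 to 2. The counts cannot be told apart from chance, but they leave out how far outside a list lies. The hippocampal list lay at 99.98, at 99.96 with each peak counted once, and at 90.5 with only the wider peaks. A different share of brain regions and an immune response to MCMV therefore stay open. Infection and the number of nuclei differed together between the 2 libraries.

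The mock library held exactly 20000 called nuclei, a round number. A candidate explanation was barcodes one base apart counted as separate nuclei, but 0 pairs of barcodes 1 base apart were found within the mock list, so it has nothing to act on. The count was also 0 within the MCMV list and between the lists. The planned comparison of frequencies within and between lists could therefore not be made, and the count is no trait of the mock library. The lists share 215 barcodes. A limit in the cell calling stays open and was not tested.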
